A study of Mus musculus with 6 samples.

How the data were processed

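Gene expression was measured in 6 samples of NKp46+ cells without CD3, sorted from spleen, intestine and skin of RAG-2-deficient mice, 2 samples per tissue. Per the labels' protocols, RNA was extracted with a micro column kit, amplified and labelled with biotin, and hybridised to Illumina mouse BeadChips, and the submitters' processing notes name BeadStudio 1.5.1.3. The tables hold, for each of 46643 probes, a signal and a detection p-value. Per the file headers the signal is the deposited average bead intensity of each probe. Its values show that the background had been subtracted, with 30.7% to 32.7% of the probes of an array below 0, and that each array had been scaled to the same mean of 83.1. Neither step is described in the sources used here. The deposited detection p-value of each probe comes from the scanner software per the file headers, and how it was computed is not given in the sources used here. A second table of the series holds the same intensities before that scaling, so that each of its columns is a constant multiple of the array's own table. The unscaled signals were 1.65 and 1.58 times the scaled ones on the spleen arrays, 0.995 and 0.612 times on the intestine arrays, and 0.526 and 0.643 times on the skin arrays. The unscaled mean signals were 137 and 131 (spleen), 82.7 and 50.9 (intestine) and 43.7 and 53.4 (skin), and the unscaled medians 3.17, 3.03, 1.94, 1.62, 1.59 and 1.67. Signal over background was thus highest on the spleen arrays, where 39.2% and 39.7% of probes were detected against 35.5% and 32.8% on the intestine arrays and 32.6% and 35.3% on the skin arrays, and dim genes are measured less well on those of intestine and skin. No genome build enters, since nothing was aligned.

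The plan assumed unnormalized scanner signals and their normexp correction. As the tables were already background-subtracted and scaled, the fallback written in the plan was used. An offset of 16 was added to each signal, the log2 taken, and the arrays quantile normalized with limma 3.58.1 in R 4.3.3. Probes were kept where the detection p was under 0.01 on both arrays of at least 1 tissue, which left 18583 probes, 18187 of them with a gene symbol. Of all 46643 probes, 20147 carried a current symbol of the reference gene table (assembly GRCm38.p6, used for names only), 12968 an older symbol that it translates, 199 an ambiguous one, 11602 a symbol that it does not hold, which was kept as in the file, and 1727 none. The probe with the highest mean stood for each gene, giving 13455 genes, 3428 of them with several kept probes. Log2 differences of a named gene's other kept probes are given beside it where one of them has the other sign or is under 25% of the printed difference.

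The 3 comparisons between tissues were fitted together with limma's lmFit and eBayes on all 6 arrays with a mean per tissue, which leaves 3 residual degrees of freedom, and p-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. The moderated spread had a prior of 6.86 degrees of freedom and a prior SD of 0.15, and the median SE of a difference was 0.15. The replicate differences had SDs over genes of 0.17 in spleen, 0.31 in intestine and 0.25 in skin. With groups of 2 no other splits of the samples were counted and no test for outlying samples was run. Where the gene's probe was detected on no array of a tissue, the fold is a lower bound, taken from the mean over the lowest detected signal of each array or the gene's own value if higher.

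In all, 27 gene lists with 850 genes were used, 17 of functions and 10 of other cell types, and 25 of them had the 5 tested members needed. Lists were tested with limma's camera at a preset correlation of 0.01, adjusted over the lists of each comparison, and again with an estimated correlation and with fry, which asks whether a list moves on balance one way without setting it against other genes. With an estimated correlation camera has only the 3 residual degrees of freedom, so few lists could pass it after adjustment. A call lost there is weak evidence against a list's shift, and leaves the part played by correlation between genes undecided. The genes to name were set by rule. Per comparison these were the 8 largest differences each way among called genes detected on both arrays of the higher tissue with all 4 array differences of one sign, up to 3 called members per list (or 2 with the highest mean where none was called), and 10 fixed genes, among them Ncr1, Klrb1c, Ptprc, Cd3e, Rag2, Il22, Tbx21, Eomes and Prf1. Another of them is not reported here. The rule gave 265 pairs of gene and comparison. For length the text gives values for part of them, picked with their values in sight, while the counts of kept and lost calls cover all that were tested. A few genes outside the rule are named in the observations and were chosen after their values were seen.

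Slides were read from the array names. Slide 1 held replicate I and slide 2 replicate II of the 3 tissues, so the slide as a block and the differences within each slide are given beside the counts. Overlap between the comparisons with spleen was set beside 100 simulations of 6 unchanged arrays. Both simulated comparisons shared the 2 simulated spleen arrays. Alternatives were median scaling in place of quantile normalization, the unscaled table, an offset of 50, no filter on detection, detection at p under 0.05, detection on all 6 arrays, every probe tested, trend and robust moderation, array quality weights, at least a 2-fold difference, only the 4 arrays compared, the replicate number as a block, and each array left out. Quantile normalization without background correction turned out to be the main setting itself and was not run again. Normexp on the unscaled signals (neqc, guided by the detection p) and the deposited scaling alone were chosen after seeing the data. The procedure was tested on simulated data with 200 of the 13455 genes changed by known folds. It called 14.9%, 65.7% and 95.5% of genes changed by 1.5-fold, 2-fold and 4-fold for intestine against spleen, 8.96%, 58.2% and 97.0% for skin against spleen, and 16.4%, 73.1% and 92.4% for intestine against skin, with 5, 5 and 3 false calls. That simulation changed far fewer genes than were called in the data. It also gave each gene the same SD in all tissues, so its rates may not carry over to the data. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.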

Results

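The series measured gene expression in CD45+ NKp46+ cells without CD3 (and, as the labels spell it, NK11+), sorted from spleen, intestine and skin of 12-week-old male RAG-2-deficient C57BL/6 mice, which make no T or B cells. NKp46 is an activating receptor of natural killer (NK) cells and of part of the innate lymphoid cells (ILCs), and the comparisons ask how such cells differ between gut, skin and spleen. RNA of each tissue was hybridised to 2 Illumina mouse BeadChips, 6 arrays in all, with replicate I of the 3 tissues on slide 1 and replicate II on slide 2. Of 46643 probes, 18266 and 18530 were detected on the spleen arrays, 16549 and 15279 on the intestine arrays, and 15196 and 16477 on the skin arrays. Across genes, which are not independent replicates, the replicate arrays correlated at 0.996 for spleen, 0.986 for intestine and 0.991 for skin. Spleen and skin arrays correlated at 0.965 to 0.971 with each other, spleen and intestine arrays at 0.902 to 0.912, and intestine and skin arrays at 0.915 to 0.930. Differences below are on the log2(signal + 16) scale, which understates the change of dim genes, and are given ± the SE of the limma fit with 2 arrays per tissue, with p-values adjusted by Benjamini-Hochberg over the 13455 genes tested. Only 2 arrays per tissue limit the precision, and since nothing says that the replicates came from separate mice, the p-values measure the spread between these samples, which may be technical.

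The deleted gene and the genes behind the sort were looked at first. Rag2 gave signals of 2.88 and 6.81 on the spleen arrays, 7.84 and 13.2 on the intestine arrays, and 0.341 and 9.50 on the skin arrays, against an array mean of 83.1. Its probe may lie outside the deleted part of the gene, so these values check nothing, and Rag2 passed in no comparison (limma adjusted p = 0.158, 0.756 and 0.10), although intestine against skin passed with the slide as a block and without skin replicate II (0.76, adjusted p = 0.0178). Cd3e, which encodes the CD3 chain excluded by the sort, was detected on none of the 6 arrays. Ncr1, the gene of NKp46, was detected on all 6, at 88.2 and 52.9 in spleen, 10.8 and 14.7 in intestine, and 33.1 and 32.4 in skin. Ptprc, the gene of the sort marker CD45, fell from spleen to intestine (-0.71 ± 0.15, adjusted p = 0.00367) and to skin (-0.86 ± 0.15, adjusted p = 0.00553), although its 2 other probes gave -0.60 and -0.14 for intestine and -0.02 and 0.17 for skin. Without spleen replicate II neither call held (adjusted p = 0.0516 and 0.0777). Tbx21, which encodes the NK and ILC1 factor T-bet, did not pass in any comparison, with signals of 732 and 890, 653 and 669, and 555 and 658 in the same order. The sign of its intestine against spleen difference (-0.12 ± 0.16, adjusted p = 0.528) turned with median scaling and without spleen replicate II (0.04). Il22, a cytokine gene of ILC3s, was detected on none of the arrays.

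Gut cells carried more of the transcripts of tissue-retained lymphocytes than spleen cells and less of those of mature circulating NK cells, although 0 of the 17 list calls of this comparison held with an estimated correlation. That fit, here and below, has 3 degrees of freedom, and few lists could pass it. Itgae, the CD103 integrin chain that binds epithelial E-cadherin, was 13.8-fold higher in intestine than in spleen (log2 difference 3.79 ± 0.35, other probes 0.74 to 3.91), and Cd69, a membrane protein that opposes tissue egress, was 9.46-fold higher (3.24 ± 0.20). S1pr5, the sphingosine-1-phosphate receptor by which mature NK cells leave tissues, was 37.7-fold lower (-5.24 ± 0.15). The surface antigen gene Ly6c1 was 14.5-fold lower (-3.85 ± 0.18), and Klrg1, an inhibitory receptor of mature NK cells, 4.63-fold lower (-2.21 ± 0.13). Among these 5 genes the highest limma adjusted p was 2.02e-05. Rora, a nuclear receptor needed by ILC2s and expressed by ILC3s, was 14.1-fold higher (3.81 ± 0.19), and Eomes, a factor of conventional NK cells, was 2.13-fold lower (-1.09 ± 0.14, other probes -1.22 and -0.01).

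The strongest rises from spleen to intestine were in Dgat1, an enzyme of triglyceride synthesis (5.43 ± 0.18, or 43.2-fold), Cables1 (5.08 ± 0.20), the oxidative stress gene Osgin1 (at least 32.5-fold) and Hk2, the hexokinase that opens glycolysis (4.90 ± 0.17). Atf3, a stress-induced transcription factor (4.82 ± 0.24), the glycosyltransferase gene Gcnt2 (4.72 ± 0.18, other probes 0.20 and 2.31), the cAMP-responsive modulator Crem (4.68 ± 0.17, other probe 0.10) and Plac8 (4.60 ± 0.35) followed. The deepest falls besides S1pr5 and Ly6c1 were in the haemoglobin genes Hbb-b1 (-4.22 ± 0.23) and Hba-a1 (-3.98 ± 0.26), the chymase gene Cma1 (-3.98 ± 0.20), Denn2b (at least 11.8-fold), Gprin3 (-3.78 ± 0.14, other probe -0.91) and Pxylp1 (-3.71 ± 0.17, other probes -0.85 to -0.07). Where "at least" is written, the gene's probe was not detected in the lower tissue.

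By gene list, fixed before the data were examined, the tissue residency and ILC1 list had 16 of 21 tested members higher in intestine, 0 lower and 5 not passing (18 passing when adjusted over the list alone, median 1.5, camera adjusted p = 8.81e-08, adjusted p = 0.0936 with an estimated correlation). Its examples besides Itgae and Cd69 were the cytokine receptor Il21r (3.71 ± 0.13) and Cxcr6 (2.69 ± 0.14), the receptor of CXCL16. The lists overlap, so their calls are not independent. Cd69, Rgs1 and Rgs2 also belong to the immediate early and stress list, and Il7r, Ltb and Cxcr6 to the ILC3 list. The ILC3 list had 13 members higher, 2 lower and 5 not passing (15 adjusted over the list alone, median 0.66, camera adjusted p = 8.66e-05, adjusted p = 0.108 with an estimated correlation). Of the 32 members of the ILC3 list 20 were tested. Il22, Il17f, Lta, Ccr6 and Cxcr5 were among those not detected on both arrays of any tissue. Its members that rose included the stem cell factor receptor Kit (2.41 ± 0.13), Csf2, which encodes GM-CSF (2.68 ± 0.14), and the oxysterol receptor Gpr183 (2.93 ± 0.15). Cytokine receptors and their signalling had 20 higher, 9 lower and 3 not passing (29 adjusted over the list alone, camera adjusted p = 0.000892, adjusted p = 0.108 with an estimated correlation). Il4ra (3.19 ± 0.15) rose there with Cish, an inhibitor of STAT5 signalling (3.53 ± 0.15). Cytokines and chemokines had 18 higher, 3 lower and 6 not passing (21 adjusted over the list alone, camera adjusted p = 5.08e-06, adjusted p = 0.0936 with an estimated correlation). Areg, a ligand of the epidermal growth factor receptor, led them (12.6-fold, 3.66 ± 0.14). Of the NK and ILC transcription factors 22 rose, 11 fell and 9 did not pass (35 adjusted over the list alone, camera adjusted p = 0.0353, adjusted p = 0.25 with an estimated correlation). That list's call ended without intestine replicate I (adjusted p = 0.0584). It held in 12 of 15 alternatives, in a range of 0.00972 to 0.0873. Here and below the 15 are camera fits at the preset correlation, so the estimated correlation and fry are not among them.

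NK receptor and maturation genes moved the other way. NK maturation and egress had 1 member higher, 16 lower and 3 not passing (18 adjusted over the list alone, median -1.48, camera adjusted p = 1.03e-07, adjusted p = 0.0936 with an estimated correlation). NK activating receptors and adaptors had 3 higher, 19 lower and 3 not passing (22 adjusted over the list alone, median -0.92, camera adjusted p = 2.89e-05, adjusted p = 0.0936 with an estimated correlation). The fallen members included Itgb2, the chain shared by the LFA-1 and Mac-1 integrins (-2.75 ± 0.15), Klrb1f (-2.47 ± 0.13), the Ly49 receptor gene Klra4 (-2.44 ± 0.17), the NK1.1 gene Klrb1c (-1.03 ± 0.14) and Ncr1 (-1.23 ± 0.18). Signals of the many near-identical Ly49 genes can reach each other's probes, so single Klra genes are uncertain. Of the inhibitory receptors 5 rose, 10 fell and 1 did not pass (16 adjusted over the list alone, camera adjusted p = 0.0588). The list passed with the slide as a block (adjusted p = 0.0459) and without spleen replicate II (adjusted p = 0.0318), in a range of 0.0154 to 0.274 over 15 alternatives. Lag3 (2.63 ± 0.18) and Lilrb4a (3.11 ± 0.18), inhibitory receptors seen on activated cells, were among those that rose. Cytotoxic effectors had 3 higher, 8 lower and 7 not passing (12 adjusted over the list alone, camera adjusted p = 0.393). The perforin gene Prf1, whose product forms pores in target cells, was at -1.22 ± 0.13, and the granzyme gene Gzmm was 4.05-fold lower.

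Immediate early and stress genes had the largest share of risen members of the tested lists, with 40 of 44 higher, 0 lower and 4 not passing (41 adjusted over the list alone, median 1.89, camera adjusted p = 6.26e-18, adjusted p = 0.186 with an estimated correlation). Nr4a3, an orphan nuclear receptor induced by receptor signalling (4.38 ± 0.22), and the NF-κB subunit Rel (3.62 ± 0.20) joined Atf3 and Cd69 there. Glycolysis and hypoxia genes had 8 higher, 3 lower and 15 not passing (9 adjusted over the list alone, camera adjusted p = 0.00625, adjusted p = 0.246 with an estimated correlation). Class II antigen presentation had 7 higher, 1 lower and 6 not passing (8 adjusted over the list alone, camera adjusted p = 0.0353, adjusted p = 0.223 with an estimated correlation). The call was lost with median scaling (adjusted p = 0.0905) and with the deposited scaling (0.0694), in a range of 0.0136 to 0.0905 over 15 alternatives. Cd83 (3.82 ± 0.13) and H2-Ab1 (2.0 ± 0.16) rose most. Cell cycle genes had 2 higher, 26 lower and 14 not passing (30 adjusted over the list alone, median -0.58, or -0.42 with undetected members at their bound, camera adjusted p = 0.000428, adjusted p = 0.305 with an estimated correlation). Nusap1, a spindle protein gene, fell (-1.33 ± 0.15), while the centromere histone gene Cenpa rose (1.69 ± 0.14). Oxidative phosphorylation had 3 higher, 19 lower and 24 not passing (22 adjusted over the list alone, camera adjusted p = 0.0483, adjusted p = 0.462 with an estimated correlation). This call was lost without spleen replicate I (adjusted p = 0.162), intestine replicate I (0.0584) or intestine replicate II (0.0760). Ribosomal proteins had 11 higher, 0 lower and 53 not passing (7 adjusted over the list alone, camera adjusted p = 0.0444, adjusted p = 0.524 with an estimated correlation). It was not called without spleen replicate II (adjusted p = 0.172), intestine replicate I (0.0547) or intestine replicate II (0.0586). Over 15 alternatives the adjusted p ran from 0.00209 to 0.196 for oxidative phosphorylation and from 1.21e-10 to 0.172 for ribosomal proteins. Interferon response genes went both ways (10 higher, 11 lower, 11 not passing, 21 adjusted over the list alone, camera adjusted p = 0.738). Their median (-0.10, above 0 with median scaling) differed in sign from their mean (0.09) and test. Chemokine and homing receptors also went both ways (9 higher, 10 lower, 7 not passing, 20 adjusted over the list alone, camera adjusted p = 0.886).

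Lists of markers of other cell types were measured beside these. Erythroid and platelet genes stood higher in spleen, with 2 members higher in intestine, 8 lower and 1 not passing (10 adjusted over the list alone, median -1.12, or -0.71 with undetected members at their bound, camera adjusted p = 0.0353, adjusted p = 0.305 with an estimated correlation). Without intestine replicate I the call was lost (adjusted p = 0.0584, range 0.00536 to 0.302 over 15 alternatives). Macrophage, monocyte and dendritic cell genes had 1 higher, 14 lower and 4 not passing (15 adjusted over the list alone, median -0.79, or -0.33 with undetected members at their bound, camera adjusted p = 0.000261, adjusted p = 0.125 with an estimated correlation). Fcgr2b, an inhibitory Fc receptor gene, fell most (-3.26 ± 0.15, other probe -0.59). T cell genes had 7 higher, 2 lower and 3 not passing (9 adjusted over the list alone, median 1.17, or 0.87 with undetected members at their bound, camera adjusted p = 0.00283, adjusted p = 0.130 with an estimated correlation). Among genes detected on all 6 arrays the call was lost (adjusted p = 0.0976), in a range of 0.000606 to 0.0976 over 15 alternatives. The largest rises were in Ctla4 (4.30 ± 0.20), Cd3g (2.35 ± 0.25) and Icos (1.95 ± 0.13). Gut epithelium had 5 higher, 0 lower and 7 not passing (3 adjusted over the list alone, camera adjusted p = 0.0353, adjusted p = 0.287 with an estimated correlation). Of its 42 members 12 were tested, and Epcam, Vil1, Fabp1, Fabp2 and Krt8 were among those not detected on both arrays of any tissue. E-cadherin (Cdh1) was at least 4.79-fold higher. The list lost its call without spleen replicate I (adjusted p = 0.0502) or intestine replicate II (0.0869), in a range of 0.009 to 0.161 over 15 alternatives. Keratinocytes (5 higher, 2 lower, 4 not passing, 7 adjusted over the list alone, camera adjusted p = 0.0713) and fibroblasts and stroma (3 higher, 1 lower, 6 not passing, 4 adjusted over the list alone, camera adjusted p = 0.125) did not pass. B and plasma cells and endothelium each had 1 member higher, 1 lower and 5 not passing (2 adjusted over the list alone, camera adjusted p = 0.738). The endothelium list's median (0.18) and mean (-0.25) differed in sign. Neutrophils (0 higher, 0 lower, 2 not passing, 0 adjusted over the list alone) and mast cells and basophils (3 higher, 1 lower, 0 not passing, 4 adjusted over the list alone) had too few tested members for camera.

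In all, 6630 genes differed between intestine and spleen, 2821 higher and 3809 lower in intestine, and 912 and 976 of them differed by at least 2-fold. With the slide as a block 7110 differed (3079 higher, 4031 lower), and at least 2-fold differences numbered 1029 higher and 1089 lower on slide 1 and 892 and 955 on slide 2. All 17 of the 25 tested lists that passed (11 up, 6 down) had medians of one sign on both slides and passed with the block, and 0 passed with an estimated correlation. The share of calls that were higher was 42.5%, against 58.5% of 7911 with median scaling, which moved the median of all genes to 0.11, and 25.7% of 7670 with the deposited scaling alone, which moved it to -0.25. Calls fell to 4008 without spleen replicate I and 4040 without spleen replicate II.

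**Figure D1:**
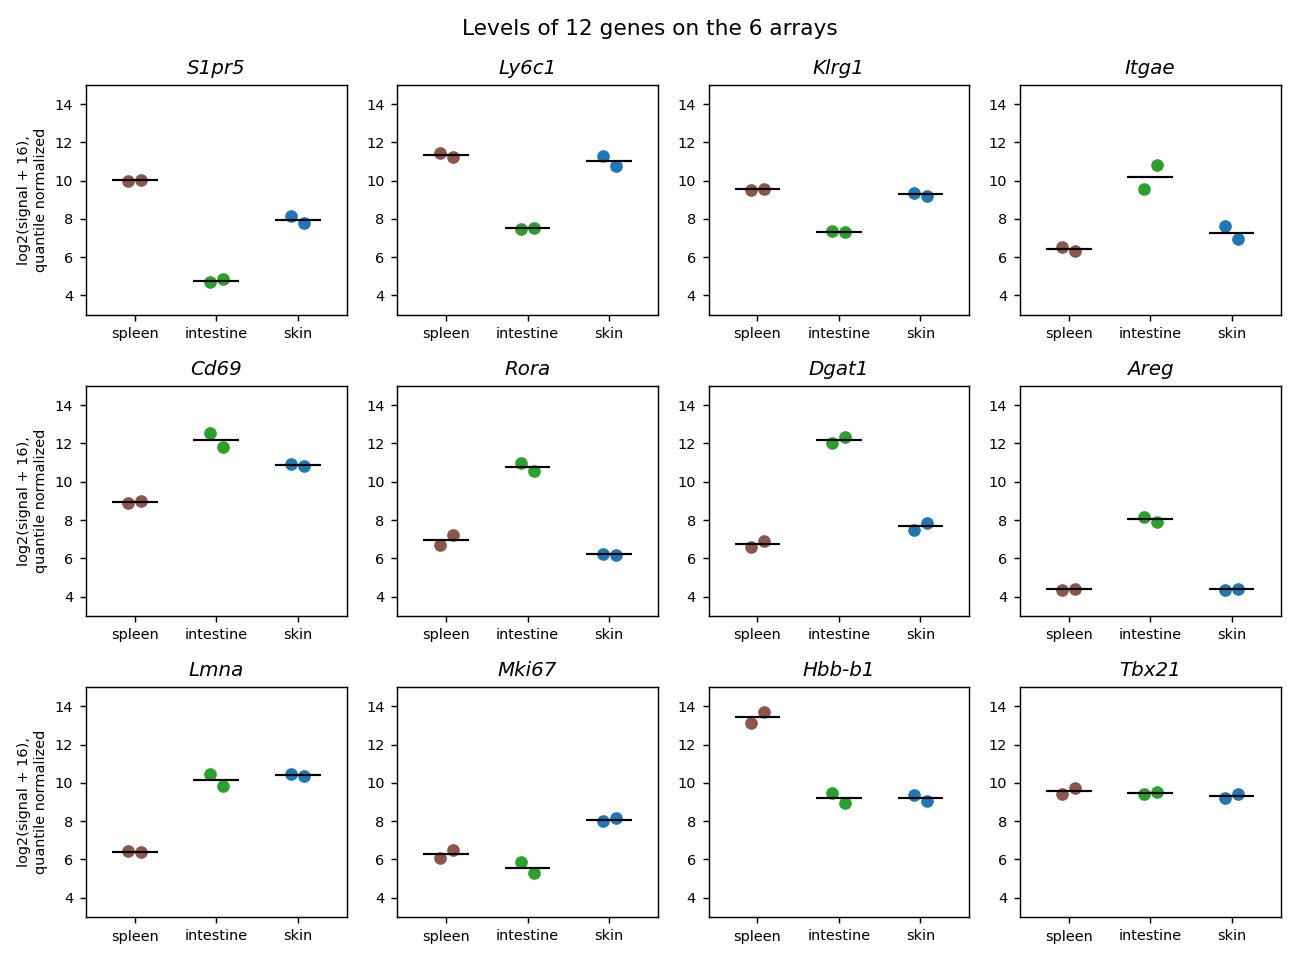
Levels of 12 genes as log2(signal + 16) after quantile normalization, with 1 point per array and a bar at the mean of the 2 arrays of spleen, intestine and skin. S1pr5, Ly6c1 and Klrg1 lie lowest and Itgae, Cd69, Rora, Dgat1 and Areg highest in intestine, Lmna is higher in both tissues than in spleen, Mki67 is highest in skin, Hbb-b1 is highest in spleen, and Tbx21 did not pass in any comparison.

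Skin cells stood closer to spleen cells, with the cell cycle, immediate early and glycolysis lists higher and the erythroid, macrophage and NK receptor lists lower at the preset correlation. With an estimated correlation 0 of the 9 list calls held (lowest adjusted p = 0.195). Lmna, which encodes lamin A and C, was 16-fold higher in skin than in spleen (4.0 ± 0.20, limma adjusted p = 9.55e-06), and the clock gene Per1 was 9.44-fold higher (3.24 ± 0.21). The proliferation marker Mki67 was 3.44-fold higher (1.78 ± 0.21). S1pr5 was 4.14-fold lower (-2.05 ± 0.15), and Hbb-b1 18.6-fold lower (-4.22 ± 0.23). The probes of Eomes differed in size of fall. Its 2 other probes read log2 levels of 8.74 and 8.86 in spleen against 7.64 and 7.87 in skin, and 6.14 and 6.40 against 5.73 and 5.56. The difference of the probe that stood for Eomes, given next, was smaller. Ncr1 (-0.53 ± 0.18, adjusted p = 0.0577, or 0.0486 without intestine replicate I or II), Eomes (-0.34 ± 0.14, adjusted p = 0.107), Prf1 (-0.21 ± 0.13, adjusted p = 0.253) and Klrb1c (-0.05 ± 0.14, adjusted p = 0.805) did not pass, and the sign of Klrb1c turned with median scaling and without spleen replicate I or skin replicate II (0.02 each).

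Besides Lmna and Per1, the largest rises in skin were in Fosb, an AP-1 subunit (2.86 ± 0.44, other probe 0.26), Spp1, which encodes the matrix protein osteopontin (2.71 ± 0.26), Rgcc, a regulator of the cell cycle (2.44 ± 0.36), Gpr183 (2.05 ± 0.15), the cell division gene Cdca3 (2.0 ± 0.14) and Bbs9, a ciliary protein gene (2.0 ± 0.14). The falls were led by Hbb-b1 and Hba-a1 (-4.04 ± 0.26), then Slc40a1, the iron exporter ferroportin (at least 4.74-fold), Alas2, the erythroid enzyme that starts haem synthesis (-2.87 ± 0.24), the heat shock genes Hspa1a (-2.66 ± 0.43) and Hspa1b (at least 5.01-fold), and the erythrocyte anion exchanger Slc4a1 (-2.22 ± 0.23). The highest limma adjusted p among these genes was 0.00407, for Hspa1a. Hspa1a and Hspa1b are near-identical copies, as are the haemoglobin genes within each family, so probes may not tell the copies apart.

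Cell cycle genes formed the clearest group, with 32 of 42 tested members higher in skin, 0 lower and 10 not passing (34 adjusted over the list alone, median 0.95, camera adjusted p = 4.21e-16, adjusted p = 0.195 with an estimated correlation). The kinetochore gene Spc24 (1.81 ± 0.20) and Birc5, which encodes survivin (1.63 ± 0.19), stood with Mki67. Immediate early and stress genes had 20 higher, 6 lower and 18 not passing (33 adjusted over the list alone, median 0.54, camera adjusted p = 0.000620, adjusted p = 0.485 with an estimated correlation). With fry, which tests against no change, the list did not pass (adjusted p = 0.130), while camera gave 4.08e-07 to 0.0109 over 15 alternatives. Cd69 rose (1.93 ± 0.20, other probes 0.23 and 1.22), and both heat shock copies were among those that fell. Glycolysis and hypoxia genes had 13 higher, 0 lower and 13 not passing (14 adjusted over the list alone, median 0.42, camera adjusted p = 0.00112, adjusted p = 0.220 with an estimated correlation). The glycolytic enzyme genes that rose included enolase 1 (Eno1, 1.01 ± 0.14), Gapdh (1.0 ± 0.13) and lactate dehydrogenase A (Ldha, 0.79 ± 0.13, adjusted p = 0.0740 without spleen replicate II). Cytokines and chemokines had 8 higher, 3 lower and 16 not passing (11 adjusted over the list alone, camera adjusted p = 0.110). Among them oncostatin M (Osm) rose (0.91 ± 0.14), and Ccl4 (0.91 ± 0.15) did so except without spleen replicate II (adjusted p = 0.0610). Cytokine receptors and signalling had 6 higher, 3 lower and 23 not passing (10 adjusted over the list alone, camera adjusted p = 0.976). Socs2 (1.97 ± 0.14, other probe 0.16) and Socs3 (1.67 ± 0.23), inhibitors of JAK-STAT signalling, rose.

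NK receptor lists moved down in skin. Inhibitory receptors had 0 higher, 9 lower and 7 not passing (10 adjusted over the list alone, median -0.50, camera adjusted p = 0.000749, adjusted p = 0.195 with an estimated correlation). Klrc1, which encodes a partner of CD94, was at -1.17 ± 0.25, and its call ended without spleen replicate I (-0.79, adjusted p = 0.118) or skin replicate II (-1.03, adjusted p = 0.0657). Activating receptors and adaptors had 2 higher, 9 lower and 14 not passing (14 adjusted over the list alone, median -0.33, camera adjusted p = 0.00556, adjusted p = 0.195 with an estimated correlation). Klrc2 fell most (-1.35 ± 0.16). Maturation and egress had 3 higher, 9 lower and 8 not passing (12 adjusted over the list alone, median -0.33, or -0.31 with undetected members at their bound, camera adjusted p = 0.00337, adjusted p = 0.207 with an estimated correlation). Cma1 (-1.94 ± 0.20) and the transcriptional repressor gene Zeb2 (-0.97 ± 0.14) fell beside S1pr5. The ILC3 list had 2 higher, 8 lower and 10 not passing (11 adjusted over the list alone, camera adjusted p = 0.0603). Kit was at -1.02 ± 0.13 and Batf3, a transcription factor gene, at -0.88 ± 0.19. The Batf3 call ended without spleen replicate I (adjusted p = 0.115), spleen replicate II (0.0726) or skin replicate I (0.0897). The list itself passed without spleen replicate I (adjusted p = 0.0481) or skin replicate I (0.0263), in a range of 0.00867 to 0.184 over 15 alternatives. NK and ILC transcription factors had 4 higher, 10 lower and 28 not passing (14 adjusted over the list alone, camera adjusted p = 0.0514). They passed as a list with the slide as a block (adjusted p = 0.0433), without spleen replicate I (0.0166) or without intestine replicate I or II (0.0482 each), in a range of 0.0136 to 0.105 over 15 alternatives.

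Several lists went both ways or stayed near 0 in skin. Tissue residency and ILC1 had 4 higher, 7 lower and 10 not passing (11 adjusted over the list alone, camera adjusted p = 0.976). Itga4, an integrin gene, was at -1.28 ± 0.14. Cytotoxic effectors had 2 higher, 3 lower and 13 not passing (8 adjusted over the list alone, camera adjusted p = 0.976). Ifng, the interferon-γ gene (0.77 ± 0.22), lost its call without spleen replicate I (0.42, adjusted p = 0.266), skin replicate I (0.150) or skin replicate II (0.0796). Chemokine and homing receptors had 4 higher, 8 lower and 14 not passing (13 adjusted over the list alone, camera adjusted p = 0.298). Interferon response had 1 higher, 5 lower and 26 not passing (6 adjusted over the list alone, camera adjusted p = 0.193). Oxidative phosphorylation had 1, 6 and 39 (2 adjusted over the list alone, camera adjusted p = 0.164), and class II presentation 2, 1 and 11 (4 adjusted over the list alone, camera adjusted p = 0.181). Ribosomal proteins had 4 higher, 4 lower and 56 not passing (2 adjusted over the list alone, camera adjusted p = 0.809). Their median of -0.002 was above 0 with median scaling and with the deposited scaling. The residency median (0.12) and mean (0.07) lay above 0 while camera placed the list down, and the median fell below 0 with the deposited scaling. The cytokine receptor median (-0.05) was below 0 while its mean (0.09) and test were above, as for T cells (median -0.03, above 0 with median scaling, mean 0.07).

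Among markers of other cells, erythroid and platelet genes had 1 higher in skin, 8 lower and 2 not passing (9 adjusted over the list alone, median -1.13, camera adjusted p = 9.36e-06, adjusted p = 0.195 with an estimated correlation). Macrophage, monocyte and dendritic cell genes had 0 higher, 14 lower and 5 not passing (14 adjusted over the list alone, median -0.79, or -0.37 with undetected members at their bound, camera adjusted p = 1.02e-06, adjusted p = 0.195 with an estimated correlation). Fcgr2b was at -1.91 ± 0.15. Fibroblast and stroma genes had 4 higher, 0 lower and 6 not passing (6 adjusted over the list alone, median 0.49, camera adjusted p = 0.00337, adjusted p = 0.195 with an estimated correlation). Thy1, also known on lymphocytes, rose most (1.86 ± 0.13). Of that list's 37 members 10 were tested, and Col1a1, Col1a2, Col3a1 and Lum were among those not detected on both arrays of any tissue. Keratinocytes (4 higher, 1 lower, 6 not passing, 9 adjusted over the list alone, camera adjusted p = 0.164), gut epithelium (2, 0 and 10, 0 adjusted over the list alone, camera adjusted p = 0.157) and T cells (2, 1 and 9, 3 adjusted over the list alone, camera adjusted p = 0.976) did not pass. Nor did endothelium (1, 0 and 6, 1 adjusted over the list alone, camera adjusted p = 0.802) or B and plasma cells (0, 2 and 5, 6 adjusted over the list alone, camera adjusted p = 0.611). Too few to test, neutrophils had 0 higher and 2 lower (2 adjusted over the list alone) and mast cells and basophils 1 higher and 2 lower (3 adjusted over the list alone).

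In all, 3300 genes differed between skin and spleen, 1763 higher and 1537 lower in skin, with 193 and 157 of them differing by at least 2-fold. With the slide as a block 3999 differed (2144 higher, 1855 lower), and at least 2-fold differences numbered 242 higher and 212 lower on slide 1 and 195 and 192 on slide 2. All 9 passing lists (4 up, 5 down) had medians of one sign on both slides and passed with the block, and 0 passed with an estimated correlation. The share of calls that were higher was 53.4%, against 71.2% of 4602 with median scaling (median of all genes 0.11) and 36.1% of 4708 with the deposited scaling alone (-0.12). Calls fell to 464 without spleen replicate I, 452 without spleen replicate II, 994 without skin replicate I and 2050 without skin replicate II, and of the 77 called genes that the naming rule picked here 42 lost their call without some array.

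**Figure D2:**
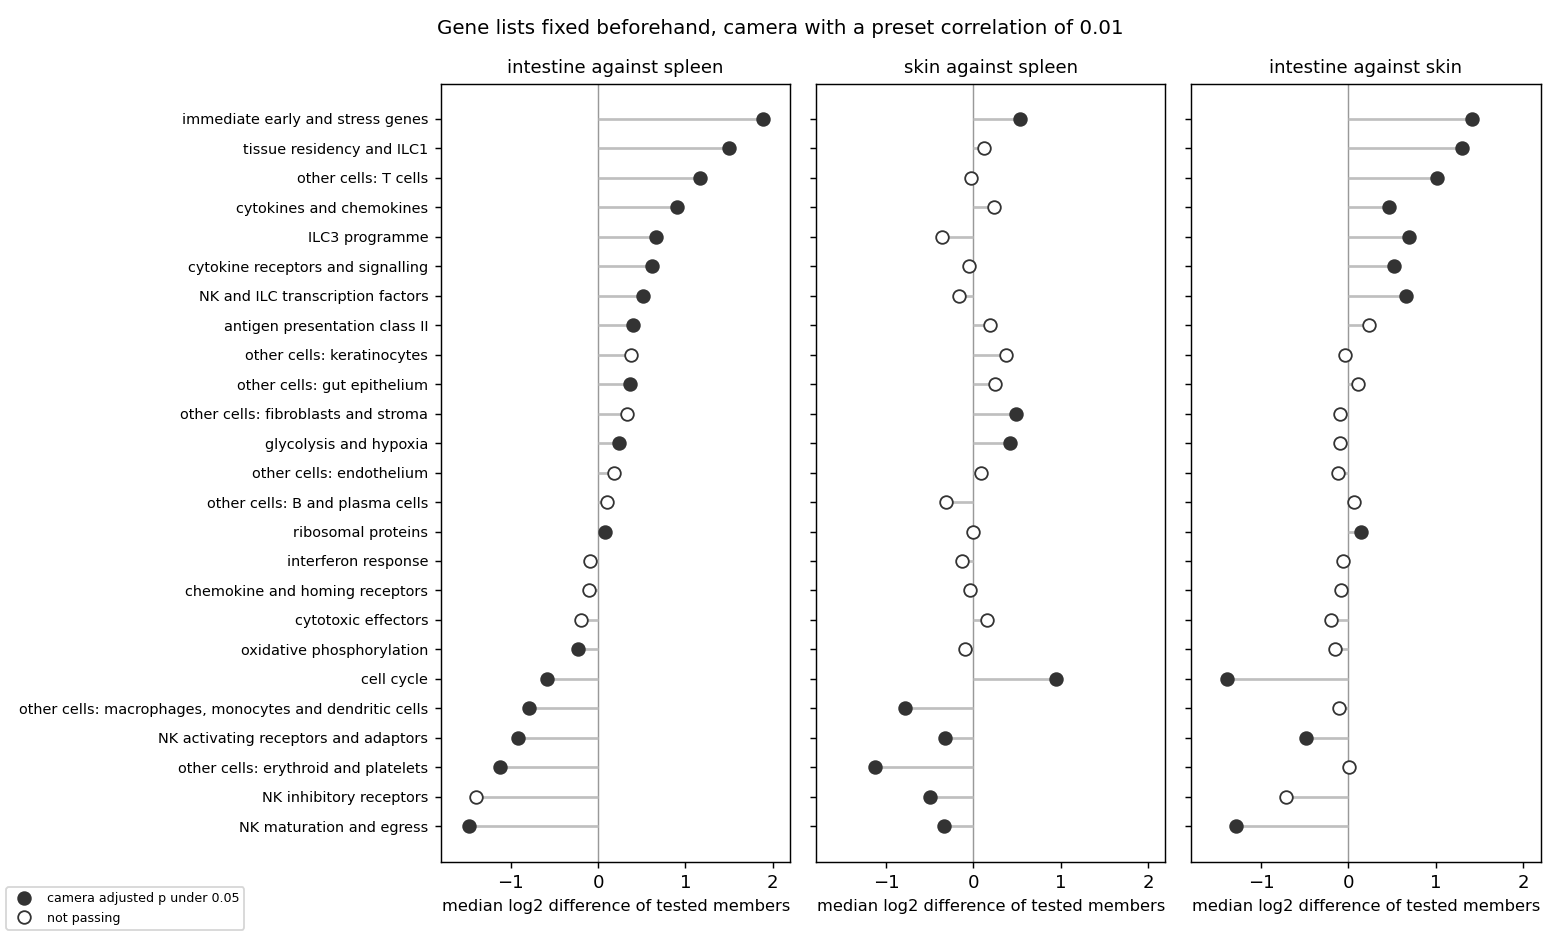
Median log2 difference of the tested members of 25 gene lists in the 3 comparisons, with filled points for a camera adjusted p under 0.05 at a preset correlation of 0.01 and open points for the others. Immediate early and stress genes lie furthest right and NK maturation genes furthest left for intestine against spleen, while for skin against spleen the cell cycle list lies furthest right and the erythroid list furthest left.

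Set against skin directly, gut cells had residency and ILC genes higher and cell division and NK maturation genes lower at the preset correlation, and 0 of the 11 list calls held with an estimated one (lowest adjusted p = 0.0964). Rora was 23.6-fold higher in intestine than in skin (4.56 ± 0.19) and Kit 10.8-fold (3.44 ± 0.13), each with a limma adjusted p of 2.86e-07 or lower. Birc5 was 7.23-fold lower (-2.85 ± 0.19), Ly6c1 11.5-fold lower (-3.52 ± 0.18) and S100a4, a calcium-binding protein gene, 13.9-fold lower (-3.79 ± 0.16). The other top genes that rose were Gcnt2 (at least 42.9-fold, other probes 0.29 and 2.56), Cables1 (5.24 ± 0.20), Osgin1 (at least 28.9-fold), the galactosyltransferase gene B3galt5 (at least 21.5-fold), Dgat1 (4.52 ± 0.18), Crem (4.38 ± 0.17, other probe 0.35) and Plac8 (4.26 ± 0.35). Those that fell were E2f2, an S-phase transcription factor (at least 9.53-fold), the semaphorin gene Sema4a (-3.38 ± 0.15), S1pr5 (-3.19 ± 0.15), Pxylp1 (-3.10 ± 0.17, while its 3 other probes gave -0.39, -0.26 and 0.02), S100a6 (-3.10 ± 0.21) and the tetraspanin gene Tspan32 (-3.02 ± 0.13).

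Tissue residency and ILC1 had 18 of 21 members higher, 0 lower and 3 not passing (19 adjusted over the list alone, median 1.3, camera adjusted p = 5.33e-12, adjusted p = 0.0964 with an estimated correlation). Asb2, which encodes part of a ubiquitin ligase (3.50 ± 0.21), and Cxcr6 (3.32 ± 0.14) were among those that rose. The ILC3 list had 13 higher, 1 lower and 6 not passing (14 adjusted over the list alone, median 0.70, or 0.50 with undetected members at their bound, camera adjusted p = 1.24e-06, adjusted p = 0.0964 with an estimated correlation). Its members besides Rora and Kit included Csf2 (3.21 ± 0.14) and Tnfsf11, which encodes the cytokine RANKL (at least 5.11-fold). NK and ILC transcription factors had 24 higher, 8 lower and 10 not passing (34 adjusted over the list alone, camera adjusted p = 0.000138, adjusted p = 0.0990 with an estimated correlation). Ikzf2, the gene of Helios, was at 3.19 ± 0.21 and the histone demethylase gene Kdm6b at 2.72 ± 0.15. Cytokine receptors (18 higher, 7 lower, 7 not passing, 27 adjusted over the list alone) and cytokines and chemokines (17, 5 and 5, 23 adjusted over the list alone) shared a camera adjusted p of 0.000138 and an adjusted p = 0.0964 with an estimated correlation. Areg was at least 11-fold and Vegfa, the vascular growth factor gene, 6.55-fold higher. Immediate early and stress genes had 34 higher, 1 lower and 9 not passing (36 adjusted over the list alone, median 1.42, camera adjusted p = 1.55e-15, adjusted p = 0.198 with an estimated correlation). Gadd45b, a stress sensor gene, was at 3.90 ± 0.17.

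Cell cycle genes had 1 higher, 36 lower and 5 not passing (37 adjusted over the list alone, median -1.39, or -1.33 with undetected members at their bound, camera adjusted p = 3.55e-14, adjusted p = 0.125 with an estimated correlation). Nusap1 (-2.83 ± 0.15) and the kinesin gene Kif22 (-2.67 ± 0.16) showed the largest falls there beside Birc5. NK maturation and egress had 3 higher, 16 lower and 1 not passing (20 adjusted over the list alone, median -1.29, camera adjusted p = 1.74e-06, adjusted p = 0.0964 with an estimated correlation). Activating receptors had 2, 15 and 8 (19 adjusted over the list alone, median -0.48, or -0.40 with undetected members at their bound, camera adjusted p = 0.00125, adjusted p = 0.0990 with an estimated correlation). The adhesion receptor Cd2 was at -1.83 ± 0.14, Klrb1c at -0.98 ± 0.14, and Ncr1 at -0.70 ± 0.18 (adjusted p = 0.0122, or 0.0516 without intestine replicate I and 0.0630 without skin replicate I). Eomes was at -0.76 ± 0.14, although its 2 other probes gave -0.18 and 0.61. Inhibitory receptors had 5 higher, 9 lower and 2 not passing (14 adjusted over the list alone, camera adjusted p = 0.490). Cytotoxic effectors had 2, 6 and 10 (9 adjusted over the list alone, camera adjusted p = 0.441). Prf1 was at -1.01 ± 0.13 and Rab27a, needed for granule release, at -1.55 ± 0.14. Ribosomal proteins had 10 higher, 0 lower and 54 not passing (7 adjusted over the list alone, median 0.15, camera adjusted p = 0.00510, adjusted p = 0.584 with an estimated correlation). The lists of glycolysis (8, 7 and 11, 15 adjusted over the list alone, camera adjusted p = 0.616), interferon response (10, 9 and 13, 20 adjusted over the list alone, camera adjusted p = 0.422) and homing receptors (11, 10 and 5, 22 adjusted over the list alone, camera adjusted p = 0.833) went both ways. Their medians (-0.10, -0.07 and -0.09, the last above 0 with median scaling) differed in sign from their means (0.19, 0.21 and 0.002) and tests. Oxidative phosphorylation (2, 9 and 35, 6 adjusted over the list alone, camera adjusted p = 0.422) and class II presentation (5, 2 and 7, 7 adjusted over the list alone, camera adjusted p = 0.0864) did not pass.

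Of the lists of other cells only T cells passed between intestine and skin, with 7 higher, 1 lower and 4 not passing (8 adjusted over the list alone, median 1.01, or 0.68 with undetected members at their bound, camera adjusted p = 0.000221, adjusted p = 0.0990 with an estimated correlation). It was led by Ctla4 (3.11 ± 0.20), Cd3g (2.68 ± 0.25) and Trat1, an adaptor of the T cell receptor (2.19 ± 0.13). Erythroid and platelet genes had 2 higher, 0 lower and 9 not passing (2 adjusted over the list alone, camera adjusted p = 0.336), and macrophage, monocyte and dendritic cell genes 1, 2 and 16 (3 adjusted over the list alone, camera adjusted p = 0.616). Gut epithelium had 2, 1 and 9 (3 adjusted over the list alone, camera adjusted p = 0.179), keratinocytes 1, 1 and 9 (2 adjusted over the list alone, camera adjusted p = 0.616), and fibroblasts and stroma 1, 3 and 6 (4 adjusted over the list alone, camera adjusted p = 0.490). Endothelium had 1, 1 and 5 (2 adjusted over the list alone, camera adjusted p = 0.853), and B and plasma cells 1, 0 and 6 (1 adjusted over the list alone, camera adjusted p = 0.490). The keratinocyte median (-0.04) differed in sign from its mean (0.21). Neutrophils had 1 higher and 1 not passing (2 adjusted over the list alone), and mast cells and basophils 2 higher, 1 lower and 1 not passing (3 adjusted over the list alone), too few to test.

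In all, 5282 genes differed between intestine and skin, 2207 higher and 3075 lower in intestine, with 828 and 705 of them differing by at least 2-fold. With the slide as a block 5703 differed (2387 higher, 3316 lower), and at least 2-fold differences numbered 1000 higher and 919 lower on slide 1 and 755 and 659 on slide 2. All 11 passing lists (8 up, 3 down) had medians of one sign on both slides and passed with the block, and 0 passed with an estimated correlation. The share of calls that were higher was 41.8%, against 30.4% of 5822 with the deposited scaling alone, where the median of all genes was -0.18. Fewer genes were called with only the 4 arrays compared (4446), with no filter (4473) and with array quality weights (4532).

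Genes that differed from spleen in both tissues were counted last. Of the genes tested, 842 were higher in both intestine and skin, where independent lists of these sizes would share 370, and 1017 were lower in both, where they would share 435. Lmna, Per1, Gpr183 and Cd69 were among the former, and S1pr5, Cma1, Fcgr2b and the haemoglobin genes among the latter. Opposite calls were fewer than independent lists would give, with 117 genes higher in intestine and lower in skin (322 for independent lists) and 174 the other way (499), Birc5 and Kit among them. In 100 simulations without any change, whose 2 comparisons shared 2 simulated spleen arrays, 0.02 genes per direction were shared on average. Without changed genes almost none are called, so this count does not measure what shared controls add to the overlap of real calls. Across genes the 2 sets of differences correlated at 0.447, against 0.50 in the simulation, and had a covariance of 0.151 against 0.0128, a difference of 0.138. The 2 spleen arrays cannot be split into parts of at least 2 arrays. Part of the excess, and of the scarcity of opposite calls, may thus come from the shared controls. The 1859 genes changed in both intestine and skin against spleen fell to 258 without spleen replicate I, 282 without spleen replicate II, 633 without skin replicate I and 1202 without skin replicate II.

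**Figure D3:**
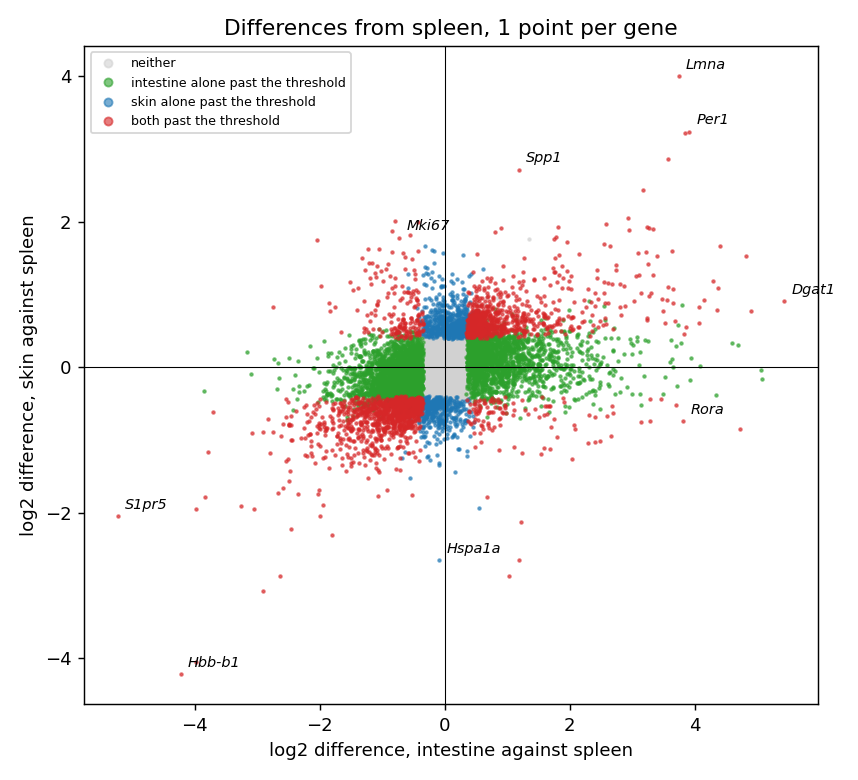
Log2 difference from spleen of each of 13455 genes, intestine on the x axis and skin on the y axis, coloured by which of the comparisons passed an adjusted p of 0.05. Lmna and Per1 lie high in both tissues, S1pr5 and Hbb-b1 low in both, Dgat1 far higher in intestine, and Rora higher in intestine but lower in skin.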

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

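The tests of stronger spleen signal, of weaker intestine signal, of handling, of T cells and of scaling were chosen only after the results they bear on were seen, and the tests of erythroid and macrophage RNA were written before their values.

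Outside the gene tests, probes for viruses that carry no gene symbol gave signal. Of 286 such probes, 14 were detected on all 6 arrays and 247 on none. A mouse mammary tumor virus probe read 91.0 and 79.6 in spleen, 94.6 and 102 in intestine, and 21.7 and 10.6 in skin, and a murine leukemia virus probe 133 and 90.7, 102 and 61.6, and 146 and 110. The mouse genome holds related endogenous sequences, and no explanation was tested.

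Erythroid and macrophage transcripts stood higher on the spleen arrays than on those of either other tissue, although the sort required CD45 and NKp46, which red cells lack. Stronger signal of the spleen arrays is argued against for the erythroid list. Against genes of the same spleen level its members differed by a median of -1.05 in intestine and -1.12 in skin, below the lowest of 1000 random sets of such genes (-0.73 and -0.48). For the macrophage list (-0.71 and -0.64) it stays open, because 12 of its 19 members were undetected in each other tissue. With undetected genes let in (no filter) the erythroid medians were -0.23 and -0.08. RNA of red cell precursors or of splenic macrophages remains a candidate source: 10% of 20 further erythroid genes and 14.3% of 14 red pulp macrophage genes were lower in both tissues, against 7.56% of all genes. The bound written beforehand for the first of these, 10% or fewer, was met and then set aside, because 13 of the 20 genes (and 9 of the 14) were detected on all 4 other arrays and their own level would hide a small share of foreign RNA. What keeps the erythroid source open is the genes' own level on the other arrays. The macrophage share of 14.3% fell between the bounds written beforehand and decides nothing. A difference between the tissues' own cells stays untested.

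Immediate early and stress genes stood highest on the intestine arrays. For the difference from skin, lower signal of those arrays is argued against. In the 3 of 4 pairs with skin in which the intestine array was the brighter one the list's median was at least 1.13. It was 1.17 in the other pair, replicate II of both, where skin was brighter, and that pair decides nothing. The difference from spleen has no such pair, since the unscaled means were 137 and 131 in spleen against 82.7 and 50.9 in intestine. The skin arrays, with means of 43.7 and 53.4, gave a list median of only 0.54 against spleen, where intestine gave 1.89. These values argue against lower signal as the whole source of the difference from spleen, and for a part of it lower signal stays open. Handling of the tissue during isolation could be a candidate cause: 47.5% of the 40 members higher in intestine (19) were also higher in skin, and 3 were lower there, which lies between the bounds of 25% and 75%. Of all 2821 genes higher in intestine than in spleen, 842 were also higher in skin. The bounds took no account of that share or of the shared spleen arrays. How each tissue was taken apart goes with the tissue, so handling and a difference of gut cells cannot be told apart here. The same limit holds for Cd69, Rgs1 and Rgs2 as members of the residency list.

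T cell genes stood higher on the intestine arrays, in mice without RAG-2 and in a sort that excluded CD3. Scaling is argued against, with a lowest list median of 0.85 over the scalings, although the median was 0.67 among genes detected on all 6 arrays, 0.69 with an offset of 50 and 0.18 with no filter. T cells with Cd3e, Cd4, Cd5, Cd6 and Tcrb transcripts are argued against as the whole source, since these genes were not detected on both intestine arrays. Of 11 list members undetected on the spleen arrays only Cd8a (9.09%) was detected on both. The 11 include Rag1, Dntt, Foxp3 and Cd4, which not every T cell expresses. The count thus does not decide about T cells with Cd8a that lack the other members. Cd3d (-0.10) and Cd28 (0.19) did not pass, and Lat (-0.42) and Cd8b1 (-0.43) were lower. Expression of Ctla4, Icos and Cd3g by the gut cells themselves stays open as a hypothesis that was not tested further.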

How the results depend on the processing

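The fits on unscaled signals with normexp and with the deposited scaling alone are tests chosen only after the results were seen. Of 245 called named differences 245 stayed called with the replicate block and with the unscaled table, 241 with normexp, 240 with the deposited scaling, 235 with median scaling, 231 with an offset of 50 and 226 with no filter. Without spleen replicate I 205 stayed, without spleen replicate II 207, without skin replicate I 215, without skin replicate II 226, and without intestine replicate I or II 241 and 242. These fits hold fewer arrays by construction. No called named difference changed sign. Of 14 named differences that were not called, 3 passed with the replicate block. Of 37 list calls 37 stayed with the block, 36 with fry, 34 with either other scaling, 33 and 34 without intestine replicate I and II, and 0 with an estimated correlation. The last fit has 3 degrees of freedom, so few lists could pass it. With detection on all 6 arrays 28 of 34 stayed. Same-numbered samples deviated together only weakly (correlations 0.16, 0.21 and 0.11), and 2 numbers cannot show pairing. The replicate block is also the slide block, which raised the counts to 7110, 3999 and 5703. Signal over background limits dim genes, least on the spleen arrays. Where no cause is named below, the cause was not tested.

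A 2-fold minimum, which is stricter by construction, left 1888, 350, 1533 and, in both tissues, 171 genes. Leaving out single arrays gave 4008 to 6705 genes for intestine against spleen, 452 to 4774 for skin against spleen and 258 to 2610 for genes changed in both intestine and skin against spleen. Skin against spleen gave 1826 genes with no filter, where more genes are tested, and 5106 with array quality weights (2.01 per spleen array, 0.559 per intestine array and 0.890 per skin array). Genes changed in both were 3264 with median scaling, 2895 with the deposited scaling and 992 with no filter. Signs turned only for values that had not passed. The list median, ribosomal proteins, skin against spleen, went from -0.002 to 0.39 with median scaling and 0.16 with the deposited scaling. The log2 difference of Tbx21, intestine against spleen, was 0.077 with median scaling and -0.29 to 0.039 without single arrays. In the same order the log2 difference of Klrb1c, skin against spleen, was 0.14 and -0.13 to 0.023, and the log2 difference of Rag2, skin against spleen, 0.20 and -0.40 to 0.21. With the deposited scaling and without single arrays the log2 difference of Mmp9, intestine against spleen, was -0.24 and -0.10 to 0.46, and the log2 difference of Ptprc, intestine against skin, -0.016 and -0.00305 to 0.30.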

Other observations

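The tests of NRF2, TGF-β and glucocorticoid lists reported here were written before the members' values were seen. The reading of the NRF2 test was changed after its result, as told at the end of this part.

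Targets of TGF-β signalling, a pathway known to shape tissue-resident lymphocytes, were compared between gut and spleen cells. Of 12 tested members that no fixed list holds, 6 were higher in gut cells, 2 lower and 4 not passing. Those that rose included Litaf (4.40 ± 0.15), the cell cycle inhibitor Cdkn1a (4.36 ± 0.18), the repressor genes Tgif1 (2.70 ± 0.16) and Ski (1.32 ± 0.15, other probe 0.33), and Pmepa1 (1.92 ± 0.13), a target that inhibits the pathway. The median was 0.64 (camera adjusted p = 0.00248 over the 5 lists written for the closing tests, adjusted p = 0.333 with an estimated correlation). Against skin the list also passed, with a smaller median of 0.27 and 5 higher, 0 lower and 7 not passing (camera adjusted p = 0.0142, adjusted p = 0.350 with an estimated correlation). Between skin and spleen it did not pass (camera adjusted p = 0.0957). Smad3 (-0.44) and Tgfbi (-0.48) fell.

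Glucocorticoid receptor targets gave a like picture in intestine, with 6 of 11 tested members higher, 1 lower and 4 not passing, and a median of 0.52 (camera adjusted p = 0.00527, adjusted p = 0.333 with an estimated correlation). Tgm2 (2.31 ± 0.14), Tsc22d3 (1.75 ± 0.17, other probe 0.11), which encodes the glucocorticoid-induced protein GILZ, Errfi1 (1.74 ± 0.13) and Klf9 (1.71 ± 0.22) rose, while Anxa1 fell (-1.75 ± 0.21). Fkbp5 (-0.08), Sgk1 (-0.04), Mt2 (0.14) and Cebpd (0.37) did not pass. Against skin 4 members were higher, 1 lower and 6 not passing (median 0.25, camera adjusted p = 0.0254, adjusted p = 0.350 with an estimated correlation). Between skin and spleen the list did not pass (3 higher, 1 lower, 7 not passing, camera adjusted p = 0.245), with Tsc22d3 higher (1.76 ± 0.17) and Tgm2 lower (-0.66, adjusted p = 0.0123) in skin.

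As hypotheses, more TGF-β signalling (median 0.64) and more glucocorticoid signalling (0.52) in gut cells may each account for a part of the difference from spleen. Both medians passed the 0.50 written beforehand, but neither call held with an estimated correlation, both lists hold Cdkn1a, and most members respond to other signals too. More NRF2 activity, raised by the rise of Osgin1, is left undecided: the median of 19 targets was -0.16 with 5 higher and 4 lower. The bound written beforehand, a median below 0.25, was met and then set aside, because its members went both ways. The TGF-β and glucocorticoid members also went both ways and spread more between intestine and spleen (SDs of 1.70 and 1.61 against 0.88). The same limit thus holds for their medians.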
